A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

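Copy number along the genome was measured by whole-genome sequencing of genomic DNA from 8 cultures, 2 genotypes at 4 times after release from a cdc7-4 block. Per the labels' protocols, DNA was purified by CsCl ultracentrifugation and libraries were made with a KAPA kit for Illumina HiSeq sequencing. The genome build was sacCer2, per the submitters' processing notes. The aligner, the read filters, the program that counted reads and the smoother were not given in the sources used here. Groups were taken from the genotype and time in the labels, with 1 library in each of the 8 groups, and nothing was pooled across libraries except where stated.

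For the 0 min libraries, the deposited values are raw read counts in windows of 1000 bp placed every 500 bp, 24133 windows in all. For later times, the authors deposited for each window a ratio of the later count to the 0 min count of the same genotype, the same ratio multiplied by a factor for each chromosome, and a smoothed form of the latter, per the file headers and the values. The meaning of each ratio was checked on the values. Multiplying the first ratio by the 0 min count gave whole reads within rounding in 100% of the windows tested, which were those with a 0 min count of at most 1000. Random values would do so in 79.7% to 88.4% of them, so that the check is a weak one for single windows. The second ratio differed from the first by a constant factor in each chromosome and had a mean of 1 on every chromosome, which removes differences between chromosomes. Windows with at most 600 counts in either library are listed at 0 in the ratios and were left out. The smoothed ratio was approximated by a local quadratic fit with tricube weights and a half-width of 12.5 kb, with a correlation over windows of at least 0.997 in each library. A further column of the later tables was not used.

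Depth was taken from the summed window counts with each read counted once, since neighbouring windows overlap. At 0 min the median count in a window was 1331 in the control and 1578 in Mcm6-SuOn. Intervals for ratios of read counts cover counting error only, at a confidence level of 95% (exact binomial), and reads without molecular identifiers are not independent molecules. Other intervals come from 1000 resamples of the 16 chromosomes and describe these libraries, not the genotypes. With 1 library per genotype and time there are no replicates, and no test between genotypes was planned. The genotypes can be paired by time, which gives 3 later pairs. An exact 2-sided sign-flip permutation test over such pairs cannot go below p = 0.25. An additive fit of genotype and time over the 8 libraries was not run.

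The 0 min libraries were compared by the ratio of read shares in windows with a summed count of at least 50, and runs of at least 2 adjacent windows beyond 1.5-fold were listed. Peaks were the highest window within 5 kb on either side with a prominence of at least 0.1. Sites were peaks of the mean of all 6 later profiles with a prominence of at least 0.05, and the value of a site was the mean of the windows within 1 kb. Local contrast divides the site value by the mean of the lowest values on its left and right up to the neighbouring sites. It was planned as an alternative to the plain site value and was given more room after the data were seen, because the plain value also takes in broad differences between the 0 min libraries. Widths were read at 50% of the height over the higher of the neighbouring lowest values, for peaks at least 0.05 high. The chromosome comparison used the first ratio divided by its library mean. Overlaps, site medians and region medians were set beside 10000 circular shifts along each chromosome, and the contrast beside 200 shifts. Genomic windows and sites are not replicates, so the shifts serve as descriptions.

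These definitions, the main measures and most alternatives were fixed before the data were examined. So was the rule for the sites named: the 10 with the highest mean over the 6 profiles, the 5 with the most negative and the 5 with the most positive difference at 30 min, and at 0 min up to 10 of the longest runs. Added after the data were seen were all settings that divide both genotypes by the pooled, the control's or the Mcm6-SuOn 0 min counts, the sites called on profiles scaled to equal SD, the joint settings of local contrast with other site sets, the contrast at shifted places, the changes over time and widths compared site by site, the comparison with chromosome ends at 75 kb, the pairing of genotypes by time, the self-made smoothing and the segment on chromosome III. Site coordinates are those of the windows in the deposited tables.

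The segment was defined as at least 10 windows in which the ratio of the genotypes, as a rolling median over 5 windows, exceeded 1.25-fold in the median over the 4 times. A first rule asked for 1.25-fold at each of the 4 times and gave 3 pieces of the same stretch, at 200501 to 212500, 213001 to 221500 and 243501 to 294000. It was replaced because it broke the stretch apart. The segment was left out wherever both genotypes were divided by a shared 0 min denominator.

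The lists of named early, late and rarely used origins, the list of centromeres, the site set of annotated origins and the names of genes at the sites need an annotation of the build, which was not used here, and these were not run. The gene table at hand belongs to another build. The high-count block on chromosome XII was placed by counts over 10 times the library median.

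The scripts were tested on simulated data, in which counts for the 24133 windows were drawn and 149 sites were planted. All times were drawn at the 0 min depth of their genotype, not at their own depth. All 149 were recovered where the planted heights were 0.3 in the control and 0.15 in Mcm6-SuOn, and the contrast difference came out at -0.130 against a true -0.128. With equal heights of 0.2 it was -0.00369, and with 0 min libraries as unequal as the real ones it was 0.00807, with 148 sites recovered. In the real data, pooling the 0 min counts moved the difference at 15 min from -0.0719 to -0.0410. The last simulation did not reproduce a shift of that size, so that it does not show unequal 0 min libraries to be harmless. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.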

Results

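Genomic DNA was sequenced from diploid budding yeast of the W303 background as cells passed from a cdc7-4 block into S phase. Cdc7 is the kinase that acts on the MCM helicase to start replication at licensed origins, and Mcm6 is a subunit of that helicase. All cells were homozygous for the temperature-sensitive cdc7-4 allele and heterozygous for Mcm6-aid, a form of Mcm6 that auxin removes. They also carried either Mcm6-ctrl or Mcm6-SuOn, the forms of Mcm6 that were compared. Cells were held in mitosis with nocodazole, treated with auxin, shifted to the restrictive temperature to block entry into S phase, and then cooled. The comparison asks how the Mcm6-SuOn form affects the copy number changes that origin firing brings about. Each genotype was sampled at 0, 15, 30 and 40 min after release, which gives 8 libraries with 1 library for each genotype and time. No difference reported here has a replicate check. Intervals cover counting error or the spread over chromosomes only, as each sentence states.

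Read depth, with each read counted once although windows overlap, was 15479784 reads in the control at 0 min and 18480968 in Mcm6-SuOn. For later times, depth was recovered from the deposited ratios and leaves out windows with low counts. The control then held 15975178 reads at 15 min, 17811495 at 30 min and 17039482 at 40 min, and Mcm6-SuOn 13791475, 16836267 and 23440860. At these depths the counting error of the ratio in a single window lay between 0.0336 and 0.0384 relative copy number units.

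Before release, most of the genome was covered alike in both strains, and most of the exceptions lay on chromosome III and near chromosome ends. Of 23511 windows compared, 380 differed by more than 1.5-fold in read share, of which 375 were higher in Mcm6-SuOn and 5 were lower. Of the higher windows, 349 formed 30 runs and 26 stood alone. Of the runs, 24 had an edge within 30 kb of a chromosome end, among them the run of 89 kb on chromosome III. Another 4 lay 31 to 44 kb from an end on chromosomes I and IX. The remaining 2 lay inside chromosome arms, at chromosome VIII 213001 to 215500 with a ratio of 2.25 (95% interval 2.07 to 2.45 for counting error) and at chromosome IV 383501 to 385000 with 1.60 (1.33 to 1.93). Of the lower windows, 2 formed a run at chromosome XVI 439001 to 440500, with a ratio of 0.666 (0.511 to 0.868). The other 3 stood alone at chromosome II 222001 and chromosome IV 518001 and 881501, each with under 60 reads in either library. These 3 inner runs were chosen for mention after their values were seen. By chromosome, the read share in Mcm6-SuOn over control was highest for chromosome III at 1.24, followed by chromosome I at 1.18 and chromosome IX at 1.11. It was lowest for chromosome XI at 0.957. Without chromosome XII and the outer 30 kb of each chromosome, 218 windows remained beyond the 1.5-fold threshold. Most of them belonged to the run on chromosome III. Outside that run and the outer 30 kb, 48 higher and 5 lower windows lay in the whole genome.

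The longest run covered chromosome III from 204001 to 293000, where 92387 control reads and 196122 Mcm6-SuOn reads gave a ratio of 1.78 with a 95% interval of 1.76 to 1.79 for counting error. The run at chromosome XIII 902001 to 918000 had a ratio of 1.75, and that at chromosome IX 18501 to 32500 had a ratio of 1.73. On chromosome I, the ratio was 1.65 over 192501 to 199500, 2.32 over 205001 to 211500 and 1.53 over 183501 to 186500. The remaining runs among the 10 longest were chromosome VI 1 to 5000 at 1.80, chromosome IX 35001 to 38500 at 1.58, chromosome XII 10001 to 13500 at 1.83 and chromosome XVI 945001 to 948062 at 2.62. The last rested on 130 control reads and 406 Mcm6-SuOn reads.

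The raised part of chromosome III was present in all 4 Mcm6-SuOn libraries and not at 0 min alone. Over a segment of 94 kb, from 200501 to 294500, the median ratio of Mcm6-SuOn over control was 1.80 at 0 min, 1.42 at 15 min, 1.44 at 30 min and 1.33 at 40 min. Each of the 187 windows was higher in Mcm6-SuOn at every time, which the choice of the segment on these times favours. The longest run, called at 0 min alone, had median ratios of 1.42, 1.44 and 1.32 at the later times, which did not enter its choice. The rest of the chromosome had median ratios between 0.968 and 1.05. The mating-type locus and the silent cassette HMR lie on this chromosome arm but were not placed against the segment, because an annotation of the build was not used here. The segment's borders were chosen after the values were seen.

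**Figure D1:**
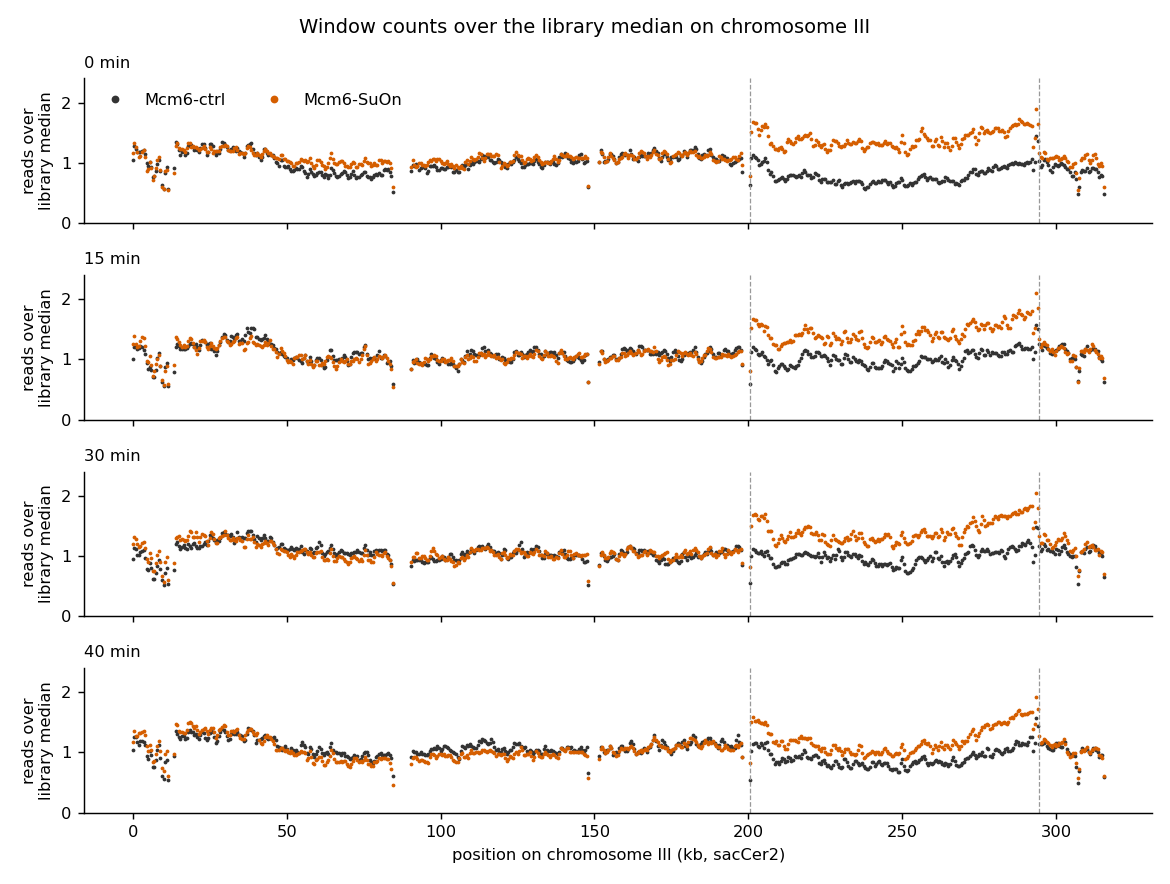
Window counts divided by the library median (vertical axis, ratio) along chromosome III (horizontal axis, kb) at each time, with control in grey and Mcm6-SuOn in orange. Dashed lines mark 200501 and 294500, between which the Mcm6-SuOn points lay above the control points at all 4 times.

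The control library at 0 min held fewer reads near chromosome ends than the other libraries. Between 20 and 30 kb from an end, its read share was lower than the mean of the other 7 libraries by a median log2 difference of -0.29. Within 75 kb of an end, compared with the rest of the genome, the difference was -0.21, against -0.03 in Mcm6-SuOn at 0 min. The 6 later libraries lay between -0.04 and 0.08 on the same measure. Each deposited ratio is taken over the same genotype's 0 min library, so that this library enters every control profile. Across windows, the ratio of the 0 min libraries, as log2 of Mcm6-SuOn over control, correlated with the control profile at r = 0.854 at 15 min, 0.785 at 30 min and 0.689 at 40 min. The same correlation was 0.439, 0.455 and -0.563 in Mcm6-SuOn. Windows are not independent replicates. Values over the pooled 0 min counts of both genotypes, a setting added after the data were seen, are therefore given beside many of the deposited ratios.

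**Figure D2:**
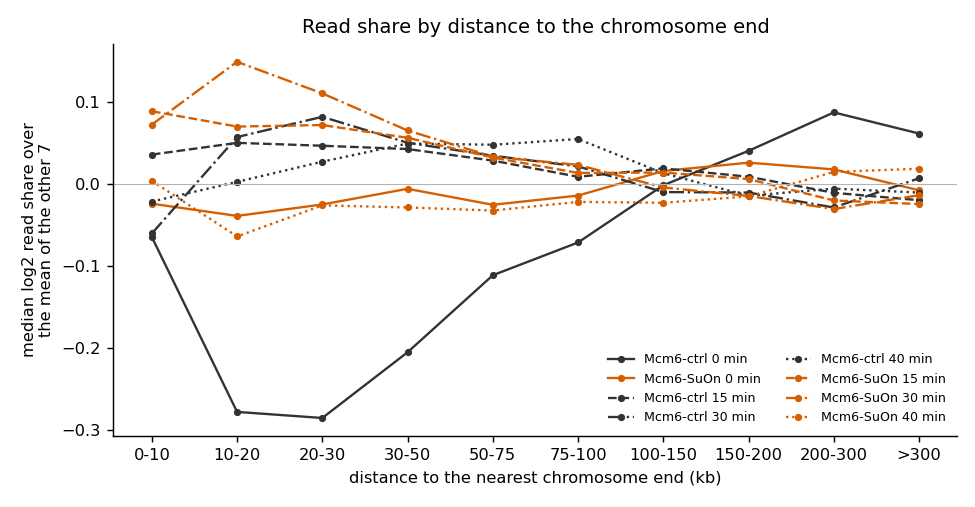
Median log2 read share of each library over the mean of the other 7 libraries (vertical axis), by distance to the nearest chromosome end (horizontal axis, kb). The control at 0 min (solid grey line) fell to -0.29 between 20 and 30 kb, and the Mcm6-SuOn 0 min library (solid orange line) stayed at -0.02 there.

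After release, relative copy number varied more along the chromosomes in control cells than in Mcm6-SuOn cells in the deposited profiles. The SD over windows in the control was 0.111 at 15 min, 0.1495 at 30 min and 0.119 at 40 min. In Mcm6-SuOn it was 0.0427, 0.0566 and 0.0648. The ratio of Mcm6-SuOn to control was 0.384 at 15 min, with an interval of 0.354 to 0.413 over resampled chromosomes, 0.379 at 30 min (0.354 to 0.406) and 0.546 at 40 min (0.485 to 0.614). Set over the pooled 0 min counts, the ratio turned at 15 min to 1.09 and moved to 0.810 at 30 min, while at 40 min it was 0.618. The difference in overall spread at 15 min therefore rested on the 0 min libraries.

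**Figure D3:**
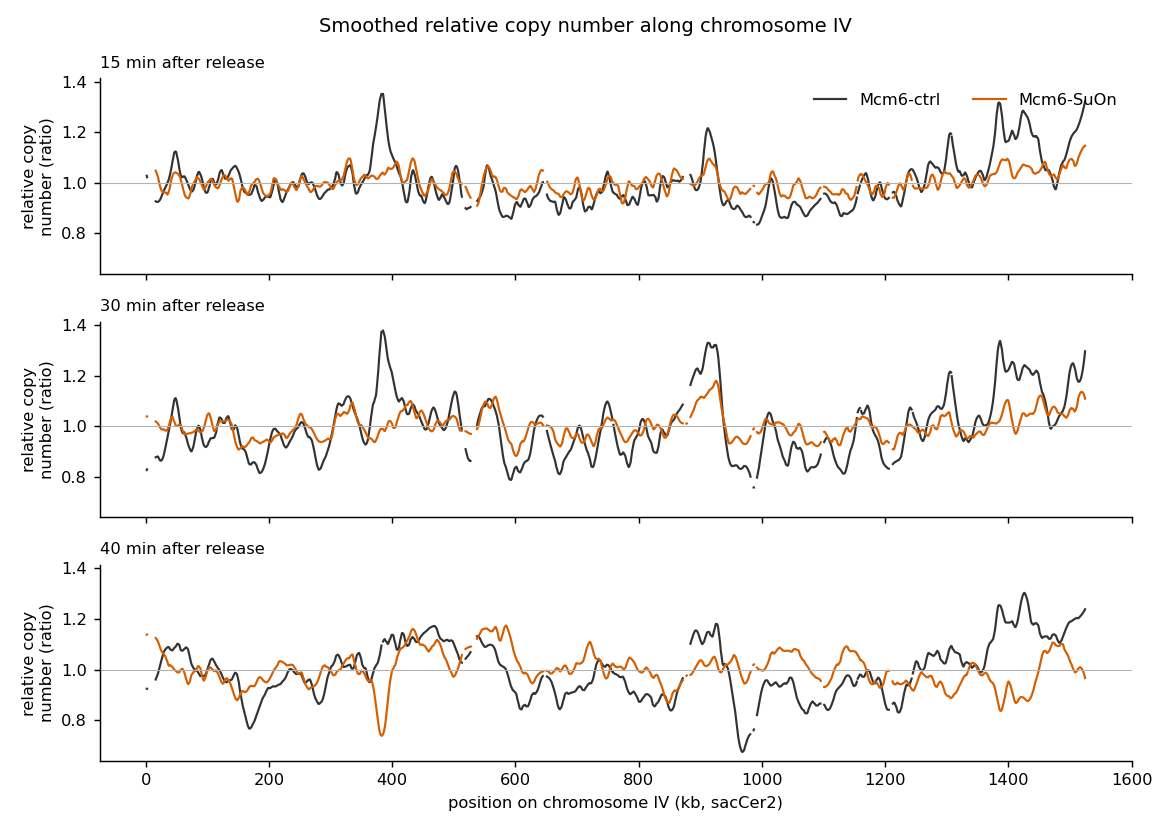
Deposited smoothed relative copy number (vertical axis, ratio) along chromosome IV (horizontal axis, kb) at 15, 30 and 40 min, with control in grey and Mcm6-SuOn in orange. At the site from 385001 to 386000 the control reached 1.34 at 15 min and 1.37 at 30 min, and Mcm6-SuOn fell to 0.745 at 40 min. This window already differed at 0 min, with 643 control and 1183 Mcm6-SuOn reads. Over the pooled 0 min counts Mcm6-SuOn minus control was 0.0761, -0.00790 and -0.0622 at 15, 30 and 40 min.

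Local peaks of copy number, which form at active origins, were more numerous in the control at 15 and 30 min. With a prominence of at least 0.1, the control had 115 peaks at 15 min, 135 at 30 min and 67 at 40 min. Mcm6-SuOn had 45, 58 and 68 peaks. The numbers over the pooled 0 min counts were 107, 136 and 57 in the control and 50, 50 and 46 in Mcm6-SuOn. The counts depended on the threshold. At a prominence of 0.05, Mcm6-SuOn had 191 peaks at 15 min and the control 201, and with Mcm6-SuOn profiles stretched to the control's range, Mcm6-SuOn had 242 peaks at 15 min, 156 at 30 min and 114 at 40 min. Stretching also enlarges the counting noise of Mcm6-SuOn and in effect lowers its threshold, so these numbers do not show more origins than in the control.

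The peaks of Mcm6-SuOn lay at control positions more often than shifted positions did at 15 and 30 min, and not at 40 min. At 15 min, 29 of 45 Mcm6-SuOn peaks (64.4%) had a control peak within 5 kb, against a mean of 4.71 after circular shifts along the chromosomes. At 30 min the number was 17 of 58 (29.3%) against 6.82, and 4 of 10000 shifts gave as many. At 40 min it was 4 of 68 (5.88%) against 3.91, and 5559 of the shifts gave as many, so that no excess overlap was detectable. The share at 40 min was 26.1% over the pooled 0 min counts. Both genotypes then have the same denominator, which by itself can raise the overlap, and no number from shifts is given for this setting. Within the control, 78 of the 115 peaks at 15 min had a peak within 5 kb at 30 min.

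At sites of raised copy number, copy number was lower in Mcm6-SuOn than in the control at 15 and 30 min, a difference that depended on how sites were chosen, more so at 15 min. The 108 sites were called on the mean of all 6 profiles, in which the control weighed more because its profiles varied more. The median of Mcm6-SuOn minus control was -0.0226 at 15 min, -0.0484 at 30 min and -0.00487 at 40 min, with 72, 89 and 57 of 108 sites lower. Intervals over resampled chromosomes were -0.0410 to -0.0138, -0.0682 to -0.0307 and -0.0447 to 0.0201, so that no difference was detectable at 40 min in the deposited ratios. Over the pooled 0 min counts it was -0.0212 at 40 min, with an interval of -0.0295 to -0.00823 and 71 of 107 sites lower. With the 6 profiles scaled to equal SD before sites were called, the differences at 123 sites were -0.00169 (-0.0151 to 0.00852), -0.0290 (-0.0415 to -0.0177) and 0.0176 (-0.00299 to 0.0346). At the 108 sites, at 15 and 30 min none of 10000 sets of shifted sites had as low a median, and at 40 min 188 had. At the 94 sites called on the Mcm6-SuOn profiles alone, the plain difference turned to 0.0321, 0.0105 and 0.0498, and a site set called on a single genotype favours that genotype.

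Measured against its own surroundings, the peak at a site stood less high in Mcm6-SuOn than in the control, with the largest difference at 30 min. Shifted places differed in the same direction by less, with values given below. Part of the difference was therefore not particular to sites. Local contrast, the site value divided by the mean of the lowest values on either side, had a median of 1.17 in the control and 1.098 in Mcm6-SuOn at 15 min. At 30 min it was 1.26 and 1.105, and at 40 min 1.14 and 1.08. The median difference was -0.0719 at 15 min, with an interval of -0.0874 to -0.0617 over resampled chromosomes. It was -0.153 at 30 min (-0.175 to -0.135) and -0.0593 at 40 min (-0.0930 to -0.0230). Mcm6-SuOn was lower at 99 of the 108 sites at 15 min, at all 108 at 30 min and at 73 at 40 min. Over the pooled 0 min counts the difference was -0.0410, -0.126 and -0.0464, with 85, 106 and 90 of 107 sites lower. At the sites of profiles scaled to equal SD it was -0.0478, -0.110 and -0.0155 with the deposited ratios, the last with an interval of -0.0420 to 0.00521, and -0.0327, -0.113 and -0.0379 over the pooled counts. At the 94 sites called on the Mcm6-SuOn profiles alone, it was -0.0130, -0.0751 and 0.0255 with the deposited ratios, with 58, 80 and 37 sites lower. Over the pooled counts it was -0.0275, -0.106 and -0.0370 at these sites.

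**Figure D4:**
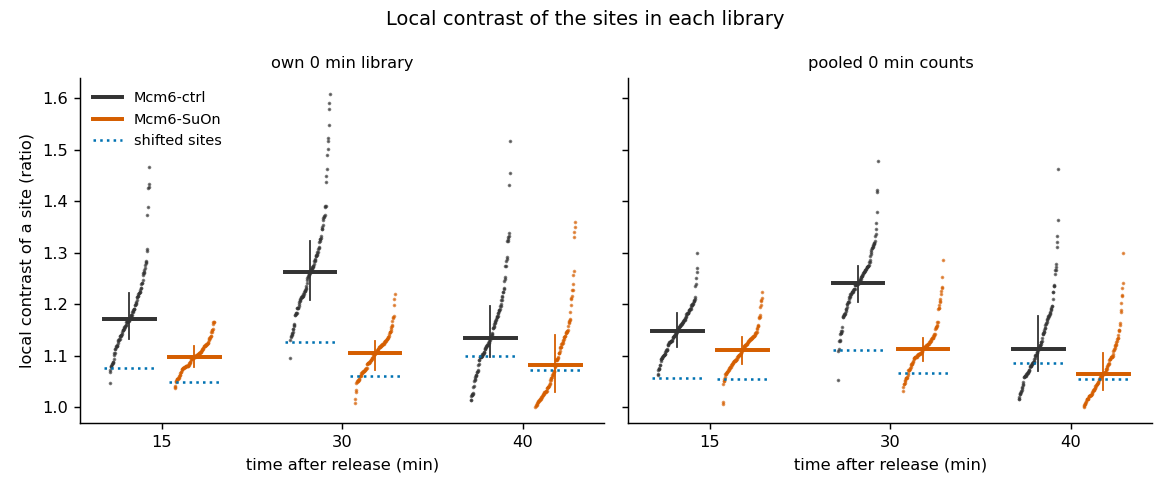
Local contrast (vertical axis, ratio) of each site in the 6 libraries by time after release (horizontal axis, min), over each genotype's own 0 min library (left) and over the pooled 0 min counts (right). Horizontal bars are medians, vertical lines are interquartile ranges over sites and dotted lines are medians at shifted places, which in Mcm6-SuOn at 40 min lay at 1.07 under a site median of 1.08.

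Local contrast rose in the control between 15 and 30 min and fell afterwards, and in Mcm6-SuOn the change over the first interval was small and not separable from 0 over the pooled 0 min counts. The median change of a site in the control was 0.101 from 15 to 30 min, with a rise at 98 of 108 sites. From 30 to 40 min it was -0.116, with a rise at 11 sites. In Mcm6-SuOn the changes were 0.00514 (interval over chromosomes 0.000171 to 0.00883), with a rise at 62 sites, and -0.00900 (-0.0285 to 0.00157), with a rise at 45 sites. Over the pooled 0 min counts the first change was 0.00334 (-0.00163 to 0.0112) and the second was -0.0452 (interval over chromosomes -0.0666 to -0.0239), with a rise at 28 of 107 sites, as the Mcm6-SuOn median went from 1.113 to 1.064. Contrast lies above 1 by construction, and at shifted places it was 1.08, 1.13 and 1.1004 in the control and 1.05, 1.06 and 1.07 in Mcm6-SuOn. Over the pooled 0 min counts, shifted places gave 1.058, 1.11 and 1.086 in the control and 1.056, 1.07 and 1.055 in Mcm6-SuOn. The genotypes thus also differed away from the sites, least at 15 min over the pooled counts. The site median exceeded that of all 200 shifts in every library except Mcm6-SuOn at 40 min, where 16 shifts gave as much. Sites were called on these same profiles, which by itself favours a contrast above that of shifted places. Mean 0 min counts at the site centre, which enter as denominators, were also low. They stood at 0.962 of the flanks 20 kb away in the control and 0.975 in Mcm6-SuOn (105 sites).

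**Figure D5:**
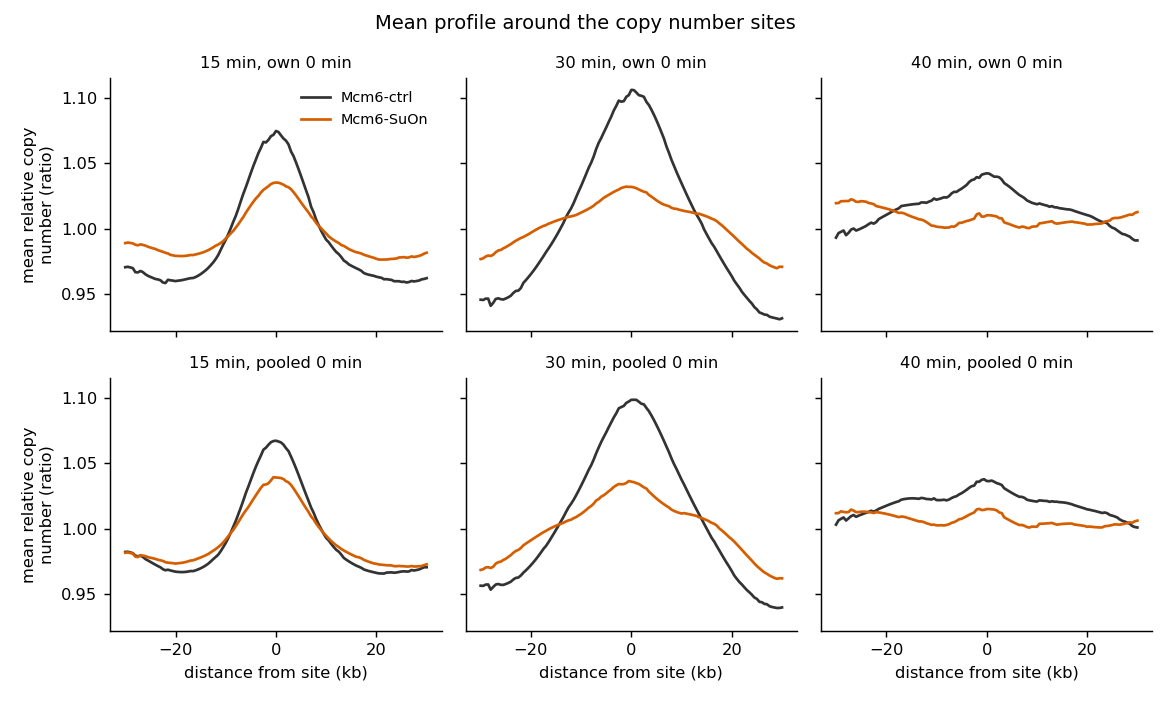
Mean relative copy number (vertical axis, ratio) by distance from the site (horizontal axis, kb) over 105 sites, with control in grey and Mcm6-SuOn in orange, over each genotype's own 0 min library (top) and over the pooled 0 min counts (bottom). At 30 min the centre reached 1.104 in the control and 1.03 in Mcm6-SuOn in the top row, against values near 20 kb of 0.965 and 0.996.

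Sites with the highest copy number differed most between the genotypes in the plain deposited values, an order that was not kept at 15 and 30 min over the pooled 0 min counts, or at any time when ranked on Mcm6-SuOn. Ranked on the mean of all 6 profiles, the 36 sites of the high class had median values of 1.16 in the control and 1.07 in Mcm6-SuOn at 15 min and 1.23 and 1.07 at 30 min. At 40 min they stood at 1.13 and 0.984. The differences were -0.0859, -0.156 and -0.126. The 36 sites of the middle class differed by -0.0379, -0.0610 and -0.0155, and those of the low class by 0.0234, -0.00804 and 0.0717. Ranking on the control profiles moved none of these 9 differences beyond its spread. That ranking favours the control by construction, and the mean of all 6 profiles already weighs the control more, so that it is not an independent check. With the local baseline, the low class turned to -0.0370 at 15 min and -0.0200 at 40 min, and the difference at 30 min was -0.186 in the high, -0.165 in the middle and -0.132 in the low class. The order at 30 min was no longer kept with the local baseline over the pooled 0 min counts, at -0.111, -0.132 and -0.135, while at 40 min it was, at -0.0662, -0.0577 and -0.0402. In the plain values over the pooled counts, the high class differed by -0.0189, -0.0593 and -0.0658 and the low class by -0.0319, -0.0593 and 0.0180. Ranked on the Mcm6-SuOn profiles alone, the differences were -0.0133, -0.0352 and 0.0296 in the high class and -0.0452, -0.0828 and -0.0581 in the low class.

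Peaks were wider at 30 than at 15 min in both genotypes, and the medians at 40 min were wider still. The median width at 50% of the height was 15.7 kb in the control at 15 min, 25.5 kb at 30 min and 36.1 kb at 40 min. In Mcm6-SuOn it was 19.1, 34.0 and 55.8 kb. At the 75 sites with a width at both times, control peaks were wider at 30 than at 15 min by a median of 7.34 kb, with an interval of 5.14 to 11.1 kb over resampled chromosomes. At 52 such sites in Mcm6-SuOn the difference was 12.6 kb (9.39 to 18.5). Over the pooled 0 min counts these changes with time were 11.1 kb (6.51 to 15.0, at 78 sites) in the control and 10.3 kb (6.99 to 15.8, at 55 sites) in Mcm6-SuOn. The order of the genotypes was thus not kept. Site by site, Mcm6-SuOn peaks were wider than control peaks by 5.93 kb at 30 min (1.55 to 11.04, at 58 sites) in the deposited profiles. At 15 min the difference was 1.89 kb (-0.329 to 2.70) and at 40 min 9.82 kb (-5.07 to 20.4, at 19 sites), neither of which was detectable against the spread over chromosomes. Only peaks at least 0.05 high entered, which left 50 control and 36 Mcm6-SuOn sites at 40 min. Over the pooled counts the differences were 2.93 kb (0.472 to 4.83), 1.97 kb (-0.827 to 8.20) and -2.42 kb (-7.02 to 9.48), so that the greater width was no longer detectable at 30 min and became detectable at 15 min. At 75% of the height the Mcm6-SuOn median was 20.9 kb at 30 min and 20.7 kb at 40 min.

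In the deposited ratios, all 10 sites with the highest mean copy number were lower in Mcm6-SuOn at 15 and 30 min, although at chromosome XIII 807501 the difference of -0.0326 at 15 min was under 2 times the counting error. The highest of all, chromosome VIII 48501 to 49500, reached 1.49 in the control and 1.09 in Mcm6-SuOn at 30 min, a difference of -0.398 with a counting error of 0.0435. Chromosome XII 416501 to 417500 stood at 1.41 in the control and 1.03 in Mcm6-SuOn. Chromosome IV held 3 of the 10 sites, with control and Mcm6-SuOn values of 1.33 and 1.14 at 914001 to 915000, 1.33 and 1.03 at 1386501 to 1387500, and 1.24 and 1.05 at 1425001 to 1426000. The values were 1.29 and 1.17 at chromosome XIII 807501 to 808500, 1.28 and 1.06 at chromosome X 711501 to 712500, and 1.29 and 1.09 at chromosome XI 644501 to 645500. They were 1.249 and 1.09 at chromosome XII 373001 to 374000. At chromosome XII 448001 to 449000, the values of 1.15 and 1.11 differed by less than 2 times the counting error, and this site was the exception at 40 min, with 1.26 in the control and 1.27 in Mcm6-SuOn. Over the pooled 0 min counts 4 of the 10 sites were higher in Mcm6-SuOn at 15 min, namely chromosome VIII 48501 by 0.00829, chromosome IV 1386501 by 0.0428 and 1425001 by 0.0602, and chromosome XI 644501 by 0.0630. At 30 min 3 were higher, with differences of 0.00339 at the chromosome XI site, 0.0760 at chromosome IV 1425001 and 0.0027 at chromosome XII 448001. A further 4 shrank by over 1.5 times at 30 min, to -0.104 at chromosome VIII 48501, -0.143 at chromosome XII 416501, -0.0387 at chromosome IV 1386501 and -0.00890 at chromosome X 711501. The remaining 3 were -0.141 at chromosome IV 914001, -0.105 at chromosome XIII 807501 and -0.151 at chromosome XII 373001.

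The 5 sites with the most negative difference at 30 min included 3 of those 10, namely chromosome VIII 48501, chromosome XII 416501 and chromosome IV 1386501. The others were chromosome IV 385001 to 386000, with 1.37 in the control and 0.988 in Mcm6-SuOn, and chromosome III 231001 to 232000, with 1.35 and 0.968. The latter lies in the raised segment and has no value over the pooled counts. Over these counts the difference at chromosome IV 385001 shrank from -0.386 to -0.00790. This site borders the inner run of chromosome IV at 0 min, and its own window had a ratio of 1.54 at 0 min. The 5 sites with the most positive difference all belonged to the low class. They were chromosome VIII 241501 to 242500 at 0.0869, chromosome XIV 255001 to 256000 at 0.0862, chromosome XVI 635001 to 636000 at 0.0671, chromosome XVI 287501 to 288500 at 0.0671 and chromosome XIV 318501 to 319500 at 0.0577. All 5 turned negative with the local baseline, to between -0.105 and -0.0366. Over the pooled counts 4 turned negative in the plain value as well, to between -0.0846 and -0.0290, and chromosome XIV 255001 shrank to 0.0324.

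In the deposited ratios, chromosome I was the chromosome with the largest difference between the genotypes after release, and chromosomes III and IX differed in the same direction. On ratios scaled to the library mean, chromosome I stood at 1.27 in the control and 1.05 in Mcm6-SuOn at 15 min, 1.26 and 1.02 at 30 min, and 1.24 and 0.911 at 40 min. Chromosome III differed by -0.121, -0.0966 and -0.136, and chromosome IX by -0.0936, -0.0886 and -0.157. These were the chromosomes with the highest Mcm6-SuOn share at 0 min, and over the pooled 0 min counts the difference for chromosome I shrank to -0.0218, -0.0406 and -0.134. At 15 min it was then exceeded by chromosome VI at -0.0436. Chromosome IX turned to 0.0208 at 15 min and 0.0238 at 30 min, and shrank to -0.0495 at 40 min. Chromosome III, without the raised segment, moved to -0.0148, 0.00934 and -0.0274.

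Regions near chromosome ends had lower relative copy number in Mcm6-SuOn in the deposited profiles. Within 30 kb of an end, the median difference was -0.116 at 15 min, -0.0941 at 30 min and -0.157 at 40 min, and none of 10000 shifted copies of the region list lay as low. Over the pooled 0 min counts the difference turned to 0.0225 at 15 min and 0.0348 at 30 min and was -0.0307 at 40 min. With a window of 15 kb it turned to 0.0320 at 30 min. The block of very high counts on chromosome XII, at 459001 to 461500, lies on the chromosome that carries the ribosomal DNA array. It took 0.803% of control reads and 0.829% of Mcm6-SuOn reads at 0 min. Its ratio over the library mean was 1.08, 1.01 and 1.14 in the control and 0.975, 1.01 and 1.204 in Mcm6-SuOn at 15, 30 and 40 min. The 30 kb on either side differed by -0.0870, -0.0243 and -0.0645, which lay at percentiles 12.9, 29.7 and 25.2 of shifted copies. Only 48, 50 and 50 windows there had values, so these medians do not cover both sides in full. These differences were -0.0515, 0.0385 and -0.00235 over the pooled counts.

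In the deposited ratios, the profiles of the genotypes resembled each other at 15 and 30 min and not at 40 min. Pearson's r across windows between control and Mcm6-SuOn was 0.730 at 15 min, 0.792 at 30 min and 0.0163 at 40 min. The Mcm6-SuOn profile at 40 min ran against the control profile of 15 min, with r = -0.404. Over the pooled 0 min counts these values were 0.892, 0.887, 0.744 and 0.209. Both profiles then have the same denominator, which by itself raises r. Unchanged libraries drawn at these depths gave 0.312, 0.345, 0.360 and 0.354 from counting error alone, with covariances of at most 4.01e-05 against observed ones of 0.00418, 0.00793, 0.00340 and 0.000740. A bias of the pooled counts would add to the observed values, and its size was not tested. With the 0 min ratio regressed out of the deposited profiles, r was 0.754, 0.789, 0.6999 and 0.165, so that the low value at 40 min depended on how the 0 min libraries were treated. The differences between the genotypes at different times shared both 0 min libraries. Their correlation was 0.881 between 15 and 30 min, 0.875 between 15 and 40 min and 0.871 between 30 and 40 min. The covariances were 0.0147, 0.0188 and 0.0240, and the 0 min ratio alone would give 0.0181. After this ratio was taken out, the correlations were 0.486, 0.0851 and 0.434, with covariances of 0.00263, 0.000532 and 0.00351.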

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

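Of the tests in this part, the one on read depth was written before its result was seen, and those on the pooled 0 min counts and on delays were chosen afterwards.

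Opposite changes over time in the genotypes singled out the following values, and none of these differences was tested. From 30 to 40 min the SD over windows changed by -0.0308 in the control and by 0.00824 in Mcm6-SuOn, but over the pooled 0 min counts it fell in both, by 0.0207 and 0.0333, while over the Mcm6-SuOn 0 min counts it went from 0.0852 to 0.0767 in the control and from 0.0568 to 0.0639 in Mcm6-SuOn. Over the same interval the number of peaks changed by -68 in the control and by 10 in Mcm6-SuOn. The rise was not kept over the pooled counts, where Mcm6-SuOn went from 50 to 46 peaks, over the control's 0 min counts (66 to 32), at a prominence of 0.05 (134 to 120) or with stretched profiles (156 to 114), and was kept over the Mcm6-SuOn 0 min counts (61 to 67), at a prominence of 0.2 (3 to 23), with each library divided by its median (60 to 68), with own smoothing (61 to 68) and without chromosome ends (56 to 67). From 15 to 30 min the median change of the site values was 0.0316 in the control and -0.00488 in Mcm6-SuOn, and 0.0302 and -0.00538 over the pooled counts.

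The lower local contrast of Mcm6-SuOn at 15 and 30 min was weighed against technical sources. The unequal 0 min libraries are argued against as the whole cause at 30 min, since the difference was still -0.126 (interval -0.139 to -0.117) with both genotypes over the same pooled counts; at 15 min it fell from -0.0719 to -0.0410, so that they could account for part of it. For read depth, the 30 min control was thinned to 94.5% of its reads, the Mcm6-SuOn depth. It then had a contrast of 1.262, against 1.263 unthinned and 1.105 in Mcm6-SuOn. At 15 min the control thinned to 86.3% had 1.173, against 1.171 unthinned. Thinning of this size could hardly have lowered the contrast to the Mcm6-SuOn value, so this test weighs little on the question of depth. A pure delay of 15 min would bring Mcm6-SuOn at 30 min to the control's level of 15 min, but it stayed below by a median of -0.0356 (-0.0459 to -0.0272) over the pooled counts; a longer delay would leave its peaks at 30 min no wider than the control's at 15 min, provided that peaks widen with time, but they were wider by a median of 16.5 kb (lower bound over chromosomes 12.3 kb), at 32.0 kb against 16.7 kb in the 15 min control lowered to the same contrast. Of shifts in time only delays were weighed, and an earlier course in Mcm6-SuOn was not tested. Release in fewer cells, less synchronous release and fewer firings per site remain open, as does a difference between single cultures, which 1 library per genotype and time cannot separate from the Mcm6 genotype.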

How the results depend on the processing

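Settings that divide both genotypes by the pooled, the control's or the Mcm6-SuOn 0 min counts, own smoothing, sites of profiles scaled to equal SD, and joint settings of the local baseline with other choices were chosen after the data were seen, and all others were planned. Of 454 alternative values for 109 results, 317 stayed within the spread of the main value or, for counts, within 1.5 times of it. A further 99 moved and 38 reversed. Among the 194 values for single chromosomes and named sites, 168 stayed, 12 moved and 14 reversed. The lower local contrast of Mcm6-SuOn at 30 min kept its sign under each combination of 0 min counts and site set that was run, from -0.153 to -0.0751. Shifted places were lower in Mcm6-SuOn at 30 min as well, at 1.06 against 1.13 deposited and 1.07 against 1.11 over the pooled counts. A kept sign, here or over the pairs of times below, therefore does not place the difference at sites. Leaving out chromosome ends, dividing each library by its median, own smoothing, the 5th to 95th percentile range and leaving out each chromosome in turn kept the sign of each difference they were run on, except that 7 of 48 chromosome differences, of at most 0.0155, turned without chromosome ends and 13, of at most 0.0230, with medians. Unless a cause is named, the cause was not tested. With the genotypes paired by time, local contrast was lower in Mcm6-SuOn in 3 of 3 pairs, deposited or over the pooled counts, as were the plain site difference and the SD in the deposited ratios (exact sign-flip permutation test, 2-sided p = 0.25, the smallest p such pairs can give). The SD over the pooled counts and the number of peaks in the deposited profiles were lower in 2 of 3 pairs (exact sign-flip permutation test, p = 0.5), and times are not replicates. Over the pooled counts Mcm6-SuOn had 50, 50 and 46 peaks against 107, 136 and 57 in the control, fewer at each time. With 1 library per group, no replicate could be left out. Annotated origins as the site set were not run. At a prominence of 0.2 the overlap at 15 min has no value, since Mcm6-SuOn had 0 peaks. Depth gives the ratio of a single window in 1 library a counting error near 0.0384, as 1 standard error. A difference between the genotypes carries the error of both ratios, so that differences of that size or smaller at single windows were not detectable.

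By construction, leaving out chromosome ends and chromosome XII lowered the windows beyond 1.5-fold at 0 min to 218, most of them in the run on chromosome III. The ratio of the SDs at 15, 30 and 40 min was 1.09, 0.810 and 0.618 over the pooled 0 min counts, 1.14, 0.936 and 0.649 over the control's and 0.890, 0.667 and 0.834 over those of Mcm6-SuOn.

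Peak numbers at a prominence of 0.05 were 201 and 118 in the control at 15 and 40 min, and 191, 134 and 120 in Mcm6-SuOn. At 0.2 they were 30, 54 and 22 in the control and 0, 3 and 23 in Mcm6-SuOn. Stretched to the control's range, which also enlarges counting noise, Mcm6-SuOn had 242, 156 and 114 peaks. Over the control's 0 min counts it had 74 at 15 min and 32 at 40 min. The overlap was 37.8% at 15 min and 10.3% at 30 min within 2 kb, 44.8% at 30 min within 10 kb, 0% at 30 min at a prominence of 0.2, and 26.1% at 40 min over the pooled counts, a denominator that both genotypes share. At 75% of the height, widths at 15, 30 and 40 min were 10.1, 15.8 and 20.5 kb in the control and 11.2, 20.9 and 20.7 kb in Mcm6-SuOn, a reading nearer the top by construction. Over the pooled counts the control's width at 40 min was 52.4 kb.

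The median site difference at 15, 30 and 40 min was -0.0719, -0.153 and -0.0593 with the local baseline, and 0.0321, 0.0105 and 0.0498 at sites of the Mcm6-SuOn profiles. At sites of profiles scaled to equal SD it was -0.00169, -0.0290 and 0.0176, at 15 and 30 min -0.0478 and -0.110 with the local baseline, and -0.113 at 30 min with the local baseline over the pooled counts. It was -0.0550, -0.0869 and -0.106 at sites with a prominence of 0.1. At the local baseline it was -0.0763, -0.152 and -0.0601 at sites of the control profiles, and -0.0130, -0.0751 and 0.0255 at sites of the Mcm6-SuOn profiles. With the local baseline over the pooled counts it was -0.126 at 30 min and -0.0464 at 40 min at the main sites, -0.0439 at 15 min and -0.130 at 30 min at sites called on the pooled profiles, and at 30 min -0.116 at control and -0.106 at Mcm6-SuOn sites.

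For the high class, the differences were -0.0133, -0.0352 and 0.0296 when ranked on the Mcm6-SuOn profiles and -0.0189, -0.0593 and -0.0658 over the pooled counts. With the local baseline over the pooled counts they were -0.0318 at 15 min and -0.0662 at 40 min. For the middle class they were -0.0823, -0.165 and -0.0669 with the local baseline, -0.0564 at 15 min with each library divided by its median, 0.0134 at 40 min when ranked on Mcm6-SuOn, and -0.132 at 30 min and -0.0577 at 40 min with the local baseline over the pooled counts. For the low class they were -0.0452, -0.0828 and -0.0581 when ranked on Mcm6-SuOn, -0.0370, -0.132 and -0.0200 with the local baseline, -0.0319, -0.0593 and 0.0180 over the pooled counts, and -0.0401, -0.135 and -0.0402 with both. With each library divided by its median they were 0.00643 at 15 min and -0.0208 at 30 min. Ranking on Mcm6-SuOn alone favours that genotype by construction, as ranking on the control favours the control.

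Over the pooled counts, the largest chromosome difference was 0.0436, 0.0406 and 0.134 in size. At 15 min it was that of chromosome VI. Chromosome IX reversed to 0.0208 at 15 min and 0.0238 at 30 min, and chromosome III to 0.00934 at 30 min. Chromosome ends reversed to 0.0225 at 15 min and 0.0348 at 30 min over the pooled counts, and to 0.0320 at 30 min with 15 kb. The flanks of the high-count block on chromosome XII changed to 0.0385 at 30 min and -0.00235 at 40 min over the pooled counts, to 0.0107 at 40 min with 15 kb and to -0.0381 at 30 min with each library divided by its median. The correlation of the genotypes rose over the pooled counts to 0.892 at 15 min, 0.887 at 30 min and 0.744 at 40 min, and that of the 15 min control with the 40 min Mcm6-SuOn profile reversed to 0.209. With the 0 min ratio regressed out, the latter reversed to 0.165 and the 40 min correlation rose to 0.6999. Profiles over the pooled counts share a denominator, which raises r by construction, and the cause of the other moves was not tested. With 10 kb means the 40 min correlation reversed to -0.0427.

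Among named sites at 30 min, chromosome XI 644501 reversed to 0.00339 and chromosome IV 1425001 to 0.0760 over the pooled counts. Reversals with the local baseline were -0.0899 at chromosome VIII 241501, -0.0366 at chromosome XIV 255001, -0.0588 at chromosome XVI 635001, -0.0666 at chromosome XVI 287501 and -0.105 at chromosome XIV 318501. Over the pooled counts, they were -0.0290 at chromosome VIII 241501, -0.0454 at chromosome XVI 635001, -0.0580 at chromosome XVI 287501 and -0.0846 at chromosome XIV 318501.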

Other observations

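All tests in this part were chosen after the results were seen.

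Chromosome VI was covered more deeply than the genome in every library. Its median window count over the genome median lay between 1.16 and 1.27 in the 8 libraries, with 1.22 in the control and 1.19 in Mcm6-SuOn at 0 min. Chromosome XI lay between 1.02 and 1.12. Chromosome I ranged from 0.858 in the control at 0 min to 1.06 in the library where it was highest. The other chromosomes apart from III lay between 0.950 and 1.06. The cause of these levels was not tested.

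The raised segment of chromosome III, 200501 to 294500, was weighed as a difference between the strains. Reads shared between repeats would change the level at its borders in both strains. The smallest step at the borders was 1.39 in the 4 Mcm6-SuOn libraries, while the control's steps lay between 0.960 and 1.08. However, the borders were placed by the ratio of the genotypes in these same libraries. A step shared by both strains could not have become a border, so these steps cannot decide on shared reads. Early replication in Mcm6-SuOn would leave the ratio near 1 before release, but it was 1.80 at 0 min and between 1.33 and 1.44 later. An extra copy in the Mcm6-SuOn strain is a candidate explanation, since 3 copies over 2 give 1.5 in a diploid. The 8 steps in Mcm6-SuOn lay near that value, between 1.39 and 1.52 with a median of 1.43. The choice of the borders favours high steps in Mcm6-SuOn, so their size is no separate test of an extra copy. Over its whole length the segment stood at 1.27, 1.33, 1.29 and 1.11 of the rest of the chromosome in Mcm6-SuOn and at 0.734, 0.922, 0.925 and 0.809 in the control, and whether the copy lies on chromosome III or elsewhere, or in all cells, was not tested.

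The shortage of reads near chromosome ends in the control at 0 min was weighed next. Within 75 kb of an end the control at 0 min departed from the 6 later libraries by -0.22 and Mcm6-SuOn at 0 min by -0.06. This is a difference of -0.16 on the log2 scale, although both were lower on 16 of 16 chromosomes. These values largely repeat the -0.21 and -0.03 by which the pattern was found. They are therefore no separate test of whether the Mcm6-SuOn 0 min library is the one out of place. A bias of single libraries unrelated to genotype or time stays open: the long-range deviation of the control at 0 min had a correlation of 0.757 with that of Mcm6-SuOn at 40 min, which shares neither, but also of 0.551 with Mcm6-SuOn at 0 min and of -0.544 and -0.637 with the control and Mcm6-SuOn at 30 min, and Mcm6-SuOn at 40 min was low near chromosome ends by only -0.04, against -0.21. DNA already replicated in the control before release cannot be told apart from it: the local contrast of the 0 min counts was higher in the control by 0.0592 (0.0483 to 0.0738), which taken alone would favour it, but shifted places gave 0.0581 and 91 of 200 shifts gave as much. A further measure, centre over flanks 20 kb away, was tried only after that first value had been seen, and over 7 site sets it ran from -0.0238 to 0.0292. These ends came from sites of the control and of the Mcm6-SuOn profiles, each with its own 0 min counts as denominator. Sites called on ratios of later libraries, free of 0 min counts, gave -0.00622 (-0.0183 to 0.00845), 0.000447 (-0.00593 to 0.0109) and 0.00578 (-0.00337 to 0.0157). No excess in the control was detectable at those sites.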
